A study of Mus musculus with 8 samples.

How the data were processed

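Whole kidneys of mice on postnatal day 8 were profiled by strand-specific RNA-seq from total RNA, with 4 nephron-specific Kctd1 knockout samples and 4 control littermate samples per the labels. The submitters' processing notes name Salmon, without a version, DESeq2 1.14.1 and the mm10 build, and the annotation release is not given in the sources used here. The authors deposited a table of estimated counts per gene, already rounded to whole numbers, and a table of TPM per gene with Ensembl identifiers and symbols. The count table holds no gene names. Its 47729 rows were joined in order to the 47729 distinct identifiers of the TPM table, in which 2 identifiers stand on 2 rows each. The join was checked on 13251 genes with at least 50 counts in every library: the SD over libraries of the log2 ratio of count to TPM had a median of 7.4e-04 and a maximum of 0.00862, against a median of 0.281 when the rows were shifted by 1. Over these genes the deposited counts thus follow the TPM values up to 1 factor per gene and 1 per library. Every column of both tables was used.

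Totals were 14457760 to 20741076 counts per library. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 10.3 over genes with at least 20 counts), so no library was counted as a repeat. Genes were filtered with filterByExpr, which kept 18548, libraries were scaled with TMM factors, and knockout was compared with wildtype by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust dispersion, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held genotype alone. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are scaled with the TMM factors. The biological coefficient of variation was 20.7%. Coordinates, gene lengths and GC content came from the GENCODE annotation of GRCm38, the assembly that mm10 denotes.

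Before the data were examined, 37 gene lists of kidney cell types and pathways were fixed from general knowledge. Of their 515 symbols, 512 were found in the TPM table, 2 through a table of current symbols, and 1 was not matched. The sex-linked genes were only looked at per library, and 36 lists with at least 3 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. An estimated correlation and fry were alternatives. Principal components came from the 500 most variable genes and were compared by an exact two-sided permutation test over 70 relabelings.

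The genes to be named were also set before the data were examined. They are Kctd1, Tfap2a and Tfap2b, then up to 10 rises and 10 falls with the largest change among genes past the threshold with an assigned name, at least 1 CPM in the higher group and groups that do not overlap, then the 5 rises and 5 falls with the smallest p. From a described list, up to 4 members past the threshold were named, or up to 2 with the smallest p where none passed. Any further gene is said to have been chosen after its values were seen. A member of the podocyte list that this rule picks is not reported here by name.

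The test was tried on simulated counts for the same 18548 genes with altered genes in knockout against wildtype. It recovered 19.4% of 67 genes changed 1.5-fold, 77.6% of 67 changed 2-fold and 86.4% of 66 changed 4-fold, and 7 of its 134 calls fell on unaltered genes. The genes changed by these folds were drawn from those with a mean of at least 1 CPM, so recovery among weaker genes was not tried. A list with all 17 members shifted by 0.5 (log2) was called, and 0 other lists were. Each gene was drawn independently, so this cannot show how often lists of correlated genes are called by chance. The adjusted threshold is stricter where fewer genes change, so recovery in the real data may be lower. Changes below 2-fold are therefore often missed at this depth and number of libraries.

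Alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, no filter and a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersion, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1) values deposited by the authors as TPM, each library left out in turn, other thresholds and the sex-linked genes left out. Alternatives chosen after seeing the data were leaving out the 2 libraries with Xist reads, leaving out ribosomal and mitochondrial rows, and a correction for GC content and transcript length. All 35 splits of the 8 libraries into 4 and 4 were fitted.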

Results

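Gene expression was measured by RNA-seq in whole kidneys of mice on postnatal day 8. In 4 kidneys Kctd1 had been deleted with a Six2-driven Cre recombinase, which acts in nephron progenitors and therefore reaches the epithelium of the nephron and leaves collecting duct, stroma, vessels and blood cells outside its lineage. The other 4 kidneys came from control littermates, called wildtype here. The knockout libraries held 17264065 ± 2543387 counts and the wildtype libraries 18069374 ± 2884422 counts (SD, n = 4 each), with a range over all 8 libraries of 14457760 to 20741076. The labels do not say whether each library came from a different animal, so the p-values measure the spread between these libraries. Xist, expressed from the inactive X chromosome of females, had 81994 counts in knockout 2 and 101295 in wildtype 3, and at most 151 in any other library, so each group held 1 library with the female pattern.

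The comparison asked which transcripts of the young kidney depend on Kctd1 in the nephron. Kctd1 encodes a BTB domain protein known to repress AP-2 transcription factors and lies on chromosome 18 from 14968685 to 15151446 (GRCm38, minus strand). It measured 22.4, 25.4, 25.8 and 23.5 CPM in knockout 1 to 4 and 32.1, 28.9, 32.6 and 32.6 CPM in wildtype 1 to 4. The means were 24.3 ± 1.57 and 31.6 ± 1.77 CPM (SD, n = 4 each), so the knockout kidneys kept 76.9% of the wildtype level and every knockout library lay below every wildtype library. The log2 fold change of -0.38 ± 0.09 (SE) missed the threshold over all genes (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.279) and passed it with DESeq2 (adjusted p = 0.0220, the lowest of its alternatives, which reached 0.692). These gene totals do not separate deleted from retained exons, and which exons are flanked by loxP sites is not given in the sources used here. The AP-2 genes did not pass. Tfap2b measured 107 ± 6.47 CPM in knockout and 92.1 ± 11.4 CPM in wildtype (log2 fold change 0.22 ± 0.09, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.794). Tfap2a measured 8.95 ± 1.43 and 10.2 ± 1.04 CPM (log2 fold change -0.18 ± 0.15, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.925).

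Marker genes of the distal convoluted tubule were among the 9 genes that fell in knockout kidneys. Pvalb, which encodes the calcium-binding protein parvalbumin of the early distal convoluted tubule, fell 4.02-fold, from 39.3 ± 4.31 to 9.79 ± 1.68 CPM (SD, n = 4 each; log2 fold change -2.01 ± 0.14 SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.6e-04). Slc12a3, the thiazide-sensitive sodium chloride cotransporter of that segment, fell 1.88-fold, from 464 ± 23.9 to 247 ± 30.9 CPM (log2 fold change -0.91 ± 0.09; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00634). Kng2, which encodes a kininogen, fell 1.92-fold, from 264 ± 6.19 to 137 ± 5.49 CPM, and had the smallest p of the 18548 genes tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.4e-04). The glucagon receptor gene Gcgr fell 2.13-fold, the glutathione peroxidase gene Gpx6 2.04-fold, the zinc finger transcription factor gene Sall3 1.88-fold and the fatty acid binding protein gene Fabp3 1.73-fold. Rhpn1 fell 1.68-fold, and Slc4a11, a transporter gene of the SLC4 family, fell 1.79-fold.

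The 6 genes that rose included both weakly and moderately expressed ones. Tff2, which encodes a trefoil factor of mucosal surfaces, rose 6.40-fold, from 1.07 ± 0.33 to 6.90 ± 1.82 CPM (SD, n = 4 each; log2 fold change 2.68 ± 0.28 SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00684). The beta-defensin gene Defb42 rose 4.71-fold, from 2.03 ± 0.54 to 9.61 ± 0.88 CPM (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00460), and Lipg, which encodes endothelial lipase, rose 2.95-fold, from 8.27 ± 0.80 to 24.5 ± 7.36 CPM. The tetraspanin gene Tspan1 rose 2.09-fold, from 35.6 ± 4.50 to 74.2 ± 6.26 CPM. Slc38a3, which encodes a glutamine transporter of the proximal tubule, rose 1.99-fold, from 21.5 ± 1.41 to 42.8 ± 6.32 CPM, and Mfsd4b5, of the major facilitator superfamily of transporters, rose 1.71-fold. Kng2 has the close paralog Kng1, and Defb42 and Mfsd4b5 belong to families of similar genes, and reads shared between copies were not examined.

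In all, 15 of 18548 genes passed, 6 higher and 9 lower in knockout (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and for each of the 15 every knockout library lay on 1 side of every wildtype library. Across all tested genes 4.03% separated the groups in this way, where chance gives 2.86%. Leaving out each library in turn, Pvalb, Slc12a3, Kng2, Gcgr, Rhpn1, Defb42, Tff2, Tspan1, Slc38a3 and Mfsd4b5 passed in all 8 fits. Lipg, Slc4a11, Fabp3, Gpx6 and Sall3 lost the call in at least 4 of them. The direction could not change in these fits, since the groups of the 15 do not overlap. The number of calls depended on the model and on the libraries. DESeq2 called 154 genes, 55 higher and 99 lower, with all 15 among them. At least 10 of the 99 followed a split of wildtype 1 to 3 from the other 5 libraries. Without wildtype 4 edgeR called 52, 13 higher and 39 lower. That fit leaves wildtype 1 to 3 against the knockouts, so genes of this split then follow genotype. How many of the 52 follow the split was not counted. Without knockout 3 edgeR called 29 and without wildtype 3 it called 10. Without the 2 libraries with Xist reads, Pvalb, Kng2 and Tspan1 were the 3 calls left, and with no filter on low counts or with a correction for GC content and length edgeR called 27 and 25.

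**Figure D1:**
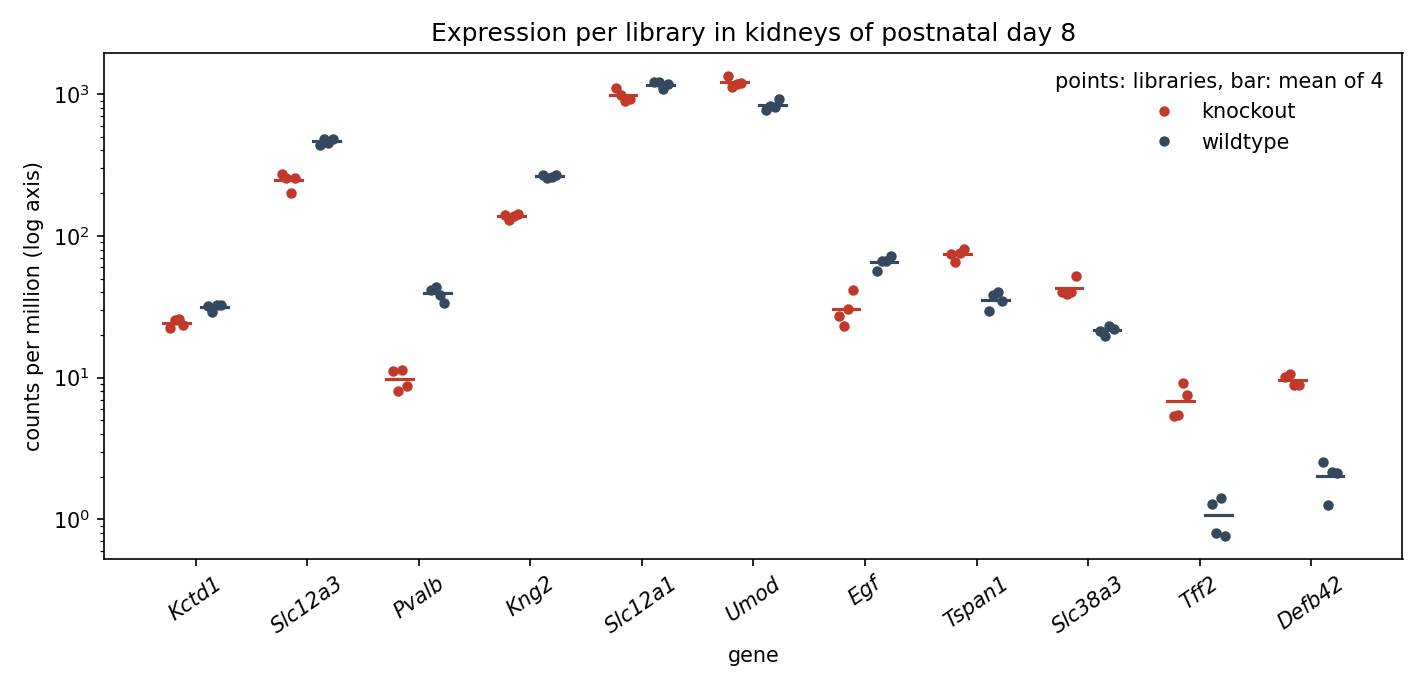
Expression of 11 genes in CPM (log axis) in the 4 knockout and the 4 wildtype libraries, with points for libraries and bars for the means. Pvalb lies between 7 and 12 CPM in knockout and above 30 CPM in wildtype, Kctd1 differs by less, and Umod and Egf move in opposite directions.

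The fixed list of distal convoluted tubule genes was lower in knockout as a group. Its 16 members had a median log2 fold change of -0.37, 15 of them negative and 1 positive (limma's camera, Benjamini-Hochberg adjusted p = 3.3e-10, and adjusted p = 0.122 with an estimated correlation). Pvalb and Slc12a3 fell, and adjusted over the list alone 9 members were lower and 1 was higher. Kcnj10, the basolateral potassium channel gene of this segment, measured 67.3 ± 6.80 CPM in knockout and 93.0 ± 3.64 CPM in wildtype, and Wnk4, a kinase gene that regulates the cotransporter, measured 158 ± 13.1 and 215 ± 22.3 CPM. Both missed the threshold over all genes with edgeR, at log2 fold changes of -0.47 ± 0.08 and -0.44 ± 0.09. Both passed with DESeq2 (adjusted p = 2.9e-04 and 0.0037), which called 6 members of the list lower and 0 higher. Kcnj10 and Wnk4 were chosen after their values were seen. The member above wildtype was Ppp1r1b, a phosphatase inhibitor gene, at 6.60 ± 1.66 against 3.50 ± 1.36 CPM, likewise chosen after its values were seen. Further along the nephron, the 10 genes of the late distal convoluted and connecting tubule had a median of -0.07, and it was not called (limma's camera, Benjamini-Hochberg adjusted p = 0.718). Of these 10 genes 0 passed with edgeR or DESeq2, and 1 was lower at an unadjusted edgeR p under 0.05.

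Thick ascending limb genes went both ways. Umod, which encodes uromodulin, the most abundant urinary protein, measured 1206 ± 96.3 CPM in knockout and 831 ± 69.1 CPM in wildtype (log2 fold change 0.54 ± 0.08, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0599). Egf, which encodes epidermal growth factor and is made in the thick ascending limb and distal convoluted tubule, measured 30.6 ± 7.78 and 65.2 ± 6.66 CPM (log2 fold change -1.09 ± 0.16, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0599). Both lay just above the threshold with edgeR and passed with DESeq2. The furosemide-sensitive cotransporter gene Slc12a1, chosen after its values were seen, measured 977 ± 89.6 against 1167 ± 59.9 CPM, with overlapping groups. Of the 16 members 0 passed with edgeR, 4 were higher and 4 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 3 lower. Adjusted over the list alone 3 were higher and 4 lower. The list as a whole was not called in a direction (median -0.13, limma's camera, Benjamini-Hochberg adjusted p = 0.358). By fry's test for change in either direction its Benjamini-Hochberg adjusted p was 2.0e-06. That test also gave values under 0.05 for other lists, so such change was not particular to this segment. Among them were distal convoluted tubule (1.7e-05), early and middle proximal tubule (0.0015) and intercalated cells (0.0074).

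Podocyte genes were lower in knockout as a group. All 12 members had negative log2 fold changes, with a median of -0.36 (limma's camera, Benjamini-Hochberg adjusted p = 8.7e-07, and adjusted p = 0.122 with an estimated correlation). Of these, 0 passed over all genes with edgeR, 5 were lower at an unadjusted p under 0.05, and DESeq2 called 4 lower. Adjusted over the list alone 4 were lower. Nphs1, which encodes nephrin of the slit diaphragm, measured 56.4 ± 9.21 CPM in knockout and 81.6 ± 6.36 CPM in wildtype (SD, n = 4 each), at a log2 fold change of -0.53 ± 0.12. The called gene Rhpn1, known from podocytes, was not in the list.

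The list of tubular injury genes was the only 1 of 36 called higher. Of its 20 tested members 17 had positive log2 fold changes, with a median of 0.14 (limma's camera, Benjamini-Hochberg adjusted p = 0.00144, and adjusted p = 0.155 with an estimated correlation). Of these, 0 passed over all genes with edgeR or DESeq2, and 5 were higher at an unadjusted edgeR p under 0.05. Adjusted over the list alone 3 were higher. Clu, which encodes the chaperone clusterin, measured 246 ± 18.9 CPM in knockout and 197 ± 19.0 CPM in wildtype. The keratin gene Krt20 measured 2.57 ± 0.77 and 1.32 ± 0.21 CPM, and is also a urothelial marker held in that list.

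Another 4 lists were called lower. The 8 thin limb genes had a median of -0.22, with Slc4a11 the 1 member that fell (limma's camera, Benjamini-Hochberg adjusted p = 0.0338, and adjusted p = 0.509 with an estimated correlation). The 19 nuclear genes of mitochondrial electron transport had a median of -0.14, all 19 negative (limma's camera, Benjamini-Hochberg adjusted p = 5.7e-04, and adjusted p = 0.587 with an estimated correlation). Of them 0 passed with edgeR or DESeq2, and 2 were lower at an unadjusted edgeR p under 0.05. The 14 endothelial genes had a median of -0.12 (limma's camera, Benjamini-Hochberg adjusted p = 0.0229) and the 16 interferon response genes one of -0.14 (adjusted p = 0.0322), and both had adjusted p = 0.542 with an estimated correlation. The calls for distal convoluted tubule, podocyte and tubular injury genes held in all 8 fits that left out a library, with medians of -0.42 to -0.27, -0.50 to -0.29 and 0.098 to 0.23. With fry the distal convoluted tubule (adjusted p = 0.0112) and podocyte lists (0.0242) passed, and the tubular injury list did not (0.0919). Mitochondrial genes lost the call without knockout 2 (median -0.058, limma's camera, Benjamini-Hochberg adjusted p = 0.0709), the library with 5.39% of its counts on the ribosomal RNA row Rn18s-rs5, against 0.36% to 1.1% in the others. Thin limb genes lost the call without knockout 3, wildtype 3 (median -0.13) or wildtype 4, with adjusted p up to 0.249, endothelial genes without knockout 1, knockout 3, wildtype 3 or wildtype 4, up to 0.155 (medians over the 8 fits -0.16 to -0.093), and interferon genes without knockout 1, knockout 2, wildtype 2 or wildtype 3, up to 0.295 (medians -0.23 to -0.11).

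**Figure D2:**
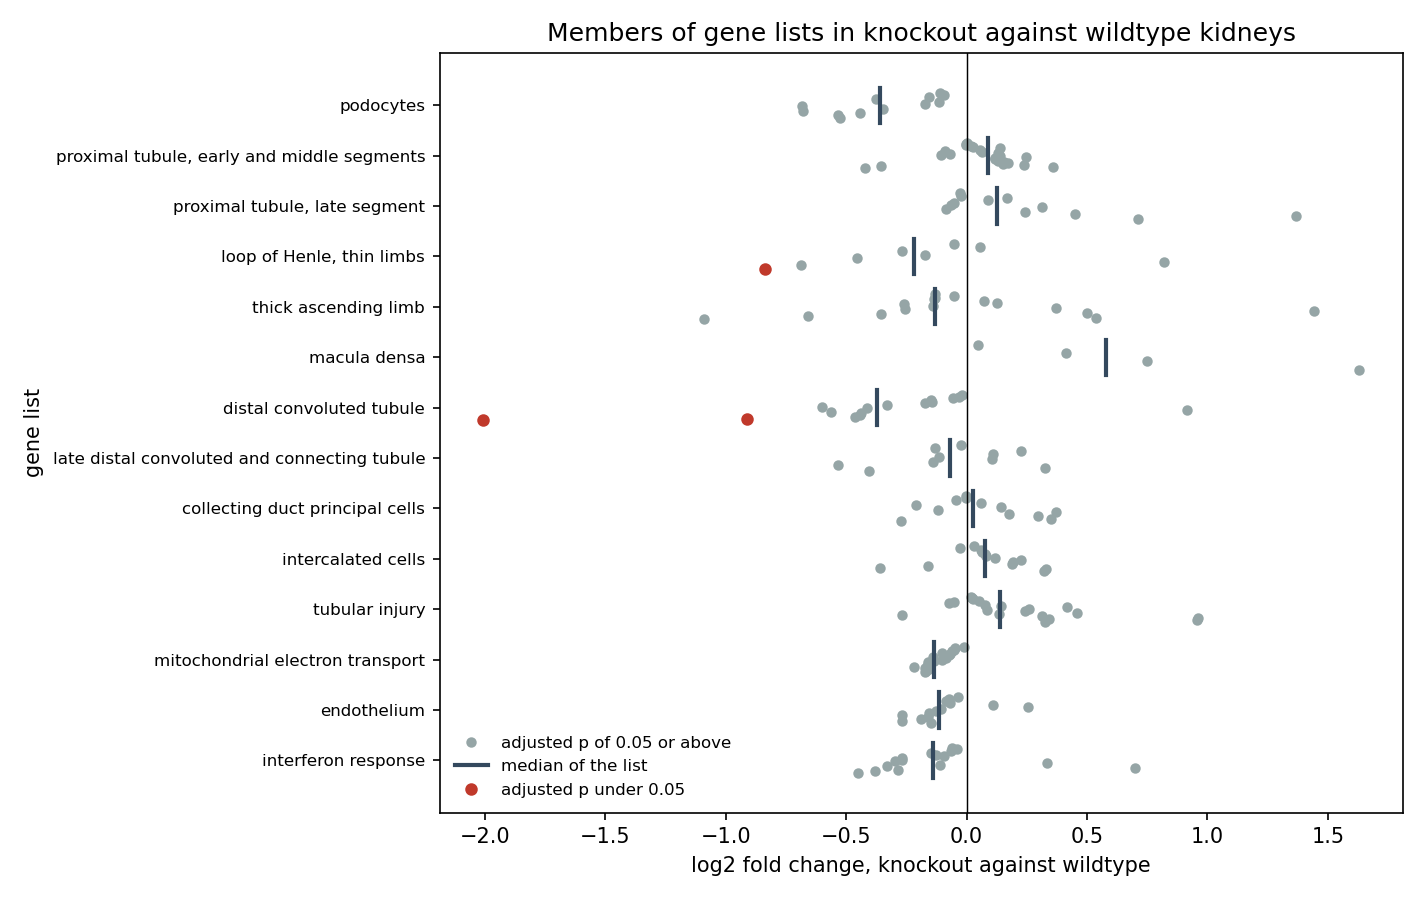
Log2 fold changes of single genes in knockout against wildtype for 14 of the gene lists, with points for members, red points for those with adjusted p under 0.05 and bars for the medians. Distal convoluted tubule and podocyte genes lie mostly left of 0 (medians -0.37 and -0.36), and thick ascending limb genes lie on both sides.

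The other 29 lists were not called. Of cell types outside the Cre lineage, the endothelium was called lower as given above (median -0.12). Those not called included collecting duct principal cells (median 0.03), stroma and fibroblasts (0.06) and macrophages (0.00). Intercalated cells, whose lineage was not examined here, were not called either (0.08). Cell cycle genes had a median of -0.01 and a mean of 0.05, targets of Wnt and beta-catenin signalling a median of -0.02 and a mean of 0.02, and the AP-2 and KCTD families a median of 0.03. The leading axis of variation was not shown to differ by genotype: principal component 1, with 20.6% of the variance of the 500 most variable genes, gave p = 0.314 in an exact two-sided permutation test. Principal component 3, with 16.1%, gave the smallest p the 70 relabelings allow, 0.0286 in the exact test, or 0.114 after Benjamini-Hochberg adjustment over 4 components.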

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

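The tests on the ratio of Pvalb to other genes and on the directions of the thick ascending limb list were chosen after those results were seen, and the correction for GC content and length was added after the data were seen; the others were set before. Among 196 sets of 4 libraries looked at, 11 held a library far from the other 3, where chance gives about 9.8 (1 in 20).

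The first pattern is the 15 genes past the threshold. Of the 35 splits of the 8 libraries, 1, the real one, gave as many genes, and the highest of the others gave 5. This argues against a chance division of the libraries as the source of the count but does not exclude it. A share of 1 in 35 is the smallest that 35 splits allow, and the other splits mix knockout and wildtype libraries. DNA inherited with the floxed allele would place calls near Kctd1, and 0 of the 15 lie within 20000000 bases of it, where 144 genes were tested; Lipg and Sall3, 2 of the 15, lie elsewhere on chromosome 18, from 74939322 and 80966376. A correction for GC content and length left 15 of the 15 past the threshold, and leaving out the rRNA-rich library knockout 2 gave a median absolute log2 fold change 0.991 times the value with it. An effect of the Kctd1 deletion stays open as a hypothesis, beside litter and other unlabelled differences between the mice, some of which are visible. Xist reads were abundant in knockout 2 and wildtype 3 alone, so this pattern was balanced at 1 library in each group. Without these 2 libraries 3 genes passed, in a fit with fewer libraries per group. All 15 kept their direction there, with absolute log2 fold changes of at least 0.72. Their groups do not overlap over the 8 libraries, so the direction could not change and does not bear on sex. Among the genes kept by the filter, 16, with 0 of the 15 among them, set wildtype 1 to 3 apart from the other 5 libraries.

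The second pattern is the lower level of distal convoluted tubule genes. The log2 ratio of Pvalb to the mean of Kcnj10, Kcnj16, Wnk4 and Klhl3 was -2.97 ± 0.31 in knockout and -1.31 ± 0.19 in wildtype (SD, n = 4 each), with a gap of 1.05 between the nearest libraries. This does not decide whether cells of the segment were fewer, since Pvalb was picked as the member with the largest change and the genes it was set against, Kcnj16 and Klhl3 among them, were chosen after their values were seen and are not confined to the segment. Leaving out knockout 2 gave a list median 1.11 times the value with it, so that library is not its source. Fewer cells of the segment, or of its early part, and lower transcription in these cells all stay open.

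The third pattern is Umod above wildtype with Slc12a1 and Egf below. The log2 ratio of Umod to Slc12a1 was 0.31 ± 0.09 in knockout and -0.49 ± 0.14 in wildtype (SD, n = 4 each). This ratio restates the pattern and decides nothing. A changed share of thick ascending limb cells alone would move the members of the fixed list the same way. Adjusted over the 16 members alone, 3 were higher and 4 lower, and without Umod, Slc12a1 and Egf 2 of 13 were higher and 2 lower, which argues against a changed share as the whole cause. After correction for GC content and length the difference of their log2 fold changes was 1.05 times the value before, which argues against such a bias as the whole cause. Altered expression within these cells, from the deletion, and a shift between kinds of thick ascending limb cells both stay open, as does a changed share as a part of the cause.

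Single libraries that stood apart are given as values. In knockout 2 Rn18s-rs5 took 5.39% of the counts, against 0.46% to 1.1% in the other knockout libraries. Mitochondrial transcripts took 5.16% in knockout 1, against 5.88% to 6.03% in the other knockouts, and 4.73% in wildtype 3, against 5.65% to 5.82% in the other wildtypes. Ren1, which encodes renin, and Lcn2 were chosen after their values were seen. Ren1 was at 8.63 log2 CPM in knockout 1 and 7.76 to 7.80 in the other knockouts. In knockout 4 Slc38a3 was at 5.71, against 5.28 to 5.34 in the other knockouts, Clu at 8.10, against 7.87 to 7.91, and Wnk4 at 7.12, against 7.35 to 7.38. Kctd1 was at 4.86 in wildtype 2, against 5.01 to 5.03 in the other wildtypes, and Lcn2 at 4.19 in wildtype 3, against 3.70 to 3.74. The mean of the late distal convoluted and connecting tubule genes was 6.88 in knockout 1, against 7.09 to 7.13, and that of the immediate early genes 3.88 in knockout 4, against 3.73.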

How the results depend on the processing

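All 15 called genes kept their direction in every alternative that gave a value for them, and of 358 such values 79 no longer passed. Since their groups do not overlap, fits on fewer libraries could not change the direction. Another 40 genes that were followed, the AP-2 genes and members of the lists, kept their direction in all 951 values and passed in 28 of them, 15 with DESeq2. Against 15 genes (6 higher, 9 lower), DESeq2 called 154 (55 higher, 99 lower), no filter 27 (11 and 16), and the correction for GC content and length, chosen after seeing the data, 25 (10 and 15). Of the 99, 10 are among the 16 genes, found among those kept by the filter, that set wildtype 1 to 3 apart from the other 5 libraries. Without the 2 libraries with Xist reads, also chosen after seeing the data, 3 genes passed, Pvalb, Kng2 and Tspan1 (1 higher, 2 lower). Limma on log2(TPM + 1) called 11 (6 lower), or 6 (2 higher, 4 lower) without a filter, and on log2(TPM + 0.1) 14, with 3, 1 and 4 of the 15 among them; the median of all genes was -0.13 on the first scale. At adjusted p under 0.1 there were 23 genes, under 0.01 9, and with an absolute log2 fold change of at least 1 7. Leaving out 1 library gave 10 to 52 genes, 5 to 13 higher and 5 to 39 lower. The 52 came without wildtype 4, where the split of wildtype 1 to 3 coincides with genotype. Kctd1 passed with DESeq2 alone (-0.38). The replicate block gave 10 genes (5 higher, 5 lower), 8 of the 15 among them, and 2 lists higher; the numbers do not pair the libraries, as same-numbered libraries correlated by -0.11 to 0.09 and 2 of 8 correlated best with their own number. Against 1 list higher and 6 lower, an estimated correlation gave 0 and 0, fry 0 and 2, the GC content and length correction 2 higher, the fit without the Xist libraries 3 lower, and leaving out 1 library 1 to 2 higher and 4 to 6 lower. The lists were not always the same: cholesterol synthesis was called lower in 5 alternatives, the replicate block, the fit without the Xist libraries (where 2 of the 6 kept the call) and 3 that left out a library; macula densa was called higher in 3, and stroma and erythroid cells in 1 each. Thin limb genes also lost the call with the replicate block (adjusted p = 0.116). The cause of these shifts was not tested, beyond fewer libraries or other genes tested. What depth alone limits was not tested. At this depth, with 4 libraries per group, the simulation recovered 19.4% of genes changed 1.5-fold, drawn from those with a mean of at least 1 CPM.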

Other observations

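Genes of the macula densa, which senses salt at the end of the thick ascending limb, had positive log2 fold changes in all 4 members, with a median of 0.58 (limma's camera, Benjamini-Hochberg adjusted p = 0.0765, and adjusted p = 0.542 with an estimated correlation). Pappa2, a protease gene of these cells, measured 124, 46.7, 23.4 and 37.2 CPM in knockout 1 to 4 and 23.3, 19.0, 9.82 and 22.8 CPM in wildtype 1 to 4, and Ptgs2 had a log2 fold change of 0.75; neither passed. Without knockout 1, the library highest in Pappa2, the median was 0.28 (adjusted p = 0.246). Without knockout 3 the list was called higher (limma's camera, Benjamini-Hochberg adjusted p = 0.0263), as it was without wildtype 4 (adjusted p = 0.0477), and over its alternatives the adjusted p ran from 0.0122 to 0.542. In the early and middle proximal tubule, adjusted over the list alone, 1 gene was higher and 2 were lower: Gatm, the first enzyme of creatine synthesis, measured 639 ± 9.24 CPM in knockout and 856 ± 87.6 CPM in wildtype, and Slc13a3, a dicarboxylate transporter gene, 184 ± 10.9 and 144 ± 17.4 CPM (SD, n = 4 each). Slc5a3, the myo-inositol transporter gene of the osmotic stress list, measured 151 ± 18.6 and 106 ± 4.89 CPM, and Itga8, of the nephron progenitor list, 109 ± 11.8 and 141 ± 1.71 CPM. Of the genes in this paragraph, Gatm, Slc5a3 and Itga8 passed with DESeq2.

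Cwc22, a splicing factor gene on chromosome 2 from 77881159 to 77946375 (GRCm38), chosen after its values were seen, measured 998, 947 and 954 CPM in wildtype 1 to 3, 36.6 CPM in wildtype 4 and 27.1 to 30.9 CPM in the knockout libraries. It passed with DESeq2 and not with edgeR. Among the 18548 genes kept by the filter, 16 were at least 2-fold higher in each of these 3 wildtype libraries than in each of the other 5. The other 55 sets of 3 libraries gave at most 9 and a median of 1. Genes that the filter left out were not searched, among them genes on chromosome 2 that DESeq2 called lower. Of the 16, 1, Cwc22 itself, lies within 10000000 bases of Cwc22, 5 lie on chromosome 2 and 11 on other chromosomes. Among them, chosen after their values were seen, are Grem1 and Scg5 on chromosome 2 and Hdx on chromosome X. DESeq2 called 10 of the 16, all lower in knockout, and edgeR called 0.

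Six2 had 2 to 6 counts in the knockout and 3 to 10 in the wildtype libraries, and Six3 had 3, 8, 3 and 6 counts in knockout 1 to 4 and 0, 4, 0 and 0 in wildtype 1 to 4. Six3 thus leaned higher in knockout, with ranges that overlap, and counts this low do not decide whether the transgene was read. Lenep, chosen after its values were seen, measured 1.49 to 2.22 CPM in the 4 knockout libraries, 0.37 CPM in wildtype 1 and 0 in the other 3 wildtype libraries, and passed with DESeq2 and not with edgeR (adjusted p = 0.140 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ttn, a sarcomere gene, measured 101 CPM in knockout 2 and at most 4.34 CPM in any other library, and Alb measured 31.7 CPM in knockout 1 and at most 1.56 CPM elsewhere, both chosen after their values were seen.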
